A study of Mus musculus with 150 samples.

How the data were processed

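The series holds 150 libraries of 3′ mRNA sequencing from the tibiae of 39 female mice, 18 aged 10 wk and 21 aged 26 wk. Per the labels, the left limb was loaded and the right limb was the control. The pieces were cancellous bone at both ages, and metaphyseal shell and mid-diaphysis at 26 wk only. Some 26 wk mice did not give all of these pieces. Per the labels the bone was flash frozen, pulverised and extracted with phenol and chloroform followed by spin columns. The notes with the series name STAR for alignment to mm10, FastQC and DESeq2, without versions. The deposited table gives 1 value per gene and library, in a unit read here as a signal, namely a read count divided by a size factor of its library. Its sheet name calls the values RPM, and the plan written before the data were examined assumed that. The library totals of the deposited values run from 868385 to 4909881, however, and dividing the values of each library by 1 factor gave whole numbers for 100% of values in the lowest library (tolerance 0.05). The whole reads recovered in this way served as counts.

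The table has 23412 rows, of which 27 carry a date in place of a gene name (at most 0.204% of reads, median 0.125%) and were left out. Of the 23385 gene rows, 4764 are at 0 in all libraries and 3479 are above 0 in every library. Reads per library run from 21303 to 17518198, with a median of 1454145.5 and a second lowest of 336452. Rn45s takes 0.161 to 48.5% of reads (median 4.98%). Intervals and errors that come from counting alone were not used: the errors given are those of the linear models and hold the spread between mice. All columns were mapped to samples, and 0 of 286 pairs of libraries compared were identical.

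Values were taken as log2 of the value plus 1, for the 13791 genes with a mean of at least 1. The factors of the deposited values look set separately within each combination of age and time. Comparisons within mice therefore used the deposited values, and the comparison of ages used values divided by common median-of-ratios factors. Linear models were fitted with limma 3.58.1 (R 4.3.3), with eBayes using a mean trend and robust settings, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. There were 28 comparisons: 16 of loaded with control limb at each age, site and time, 4 of the loading response between ages, 1 of age in control cancellous bone, 3 between sites in 26 wk control limbs and 4 of the loading response between sites by an F test. Mouse was a fixed block for loading and sites, time was a covariate for age, and the comparison of responses between sites had blocks for mouse with site and mouse with limb. Limbs were paired because both come from the same mouse. As a check on the pairing, the median correlation between both limbs of a mouse, after removal of group means, was 0.106 in cancellous bone (over 0.1 in 19 of 37 mice), 0.0748 in the shell (9 of 19) and 0.0584 in the mid-diaphysis (5 of 19). The recovered reads were also analysed with edgeR 4.0.16 (TMM factors, robust quasi-likelihood fits).

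Gene lists were written before the data were examined: 36 lists covering energy metabolism, bone, marrow and neighbouring cell types, and responses to load, stress and time of day. Of these, 35 could be tested, since the mitochondrially encoded genes are absent from the table. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, in 24 comparisons with a direction (840 tests), with adjustment within each comparison. A member counts as past the threshold when its p adjusted over all genes is under 0.05, and the count adjusted over the list alone uses the members' p values only. A further list of 12 mesothelial genes was written after the data were examined. A library was doubted where its mean log2 level over that list was above 4 (8 libraries) or where it held fewer than 100000 reads (1 library). Such libraries stayed in the reported values. Fits of loading without them also drop the other limb of the same mouse and site, so fewer mice remain. List tests without them were run at the preset correlation only.

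Named genes follow a rule fixed before the data were examined. For loading, these are the 4 highest and 4 lowest called genes, and for age and site the 6 highest and 6 lowest, with a mean of at least 5 in 1 group and the same direction in every mouse where mice are paired. Up to 4 members of a described list with the smallest p may also be named, and 6 genes known for loading are always tabulated. Of these 6, Ptgs2 fell under the filter. Genes named outside the rule are marked as chosen after their values were seen. Coordinates are those of GENCODE vM21 (mm10) and are given where a symbol has 1 position.

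The fits were tested on simulated data with 200 of 13791 genes changed in each of 3 comparisons, other genes each time. The spread of each gene was taken from the libraries that were not doubted. Genes changed in none of the 3 count as unchanged. For loading in the shell at 24 h limma called 8, 58, 72 and 88% of genes changed 2-, 4-, 8- and 16-fold, with 5 of 13191 unchanged genes called, and edgeR called 6, 60, 70 and 88% with 4. For age the limma shares were 42, 96, 100 and 100%, and for shell against cancellous bone 64, 98, 98 and 100%. With nothing changed, 6 of 386148 gene tests and 1 of 840 list tests at the preset correlation passed, and 0 at an estimated one. The simulated genes were drawn independently of each other, without differences in muscle or mesothelium content between libraries. The simulation therefore cannot tell how often lists pass in the real data. There, swapping limbs within mice let a median of 97 of 560 loading tests pass at the preset correlation.

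The alternatives planned before the data were examined were a pseudocount of 0.25, no filter, a minimum mean of 5, median-of-ratios factors, no block for mouse, a fit to the libraries of the comparison alone, loaded limbs in place of control limbs, age without the time covariate, edgeR, an estimated correlation for lists and leaving out each mouse in turn. Added after the data were examined were fits without the 9 doubted libraries, age on values as deposited, age without the 3 h and 24 h groups, a covariate for the mean of the muscle list, and leaving out each mouse for age and site. Figures were drawn with python 3.11.15. Raw reads and alignments were not used here.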

Results

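Gene expression in tibial bone was measured by 3′ mRNA sequencing in 39 female C57BL/6J mice, 18 aged 10 wk and 21 aged 26 wk. The left tibia was loaded cyclically (9 N peak load, 4 Hz, 1200 cycles per day), and the right tibia of the same mouse was the unloaded control. Mice were killed 1 h, 3 h or 24 h after 1 bout, or on day 8 of a schedule with 5 days of loading. Cancellous bone was taken at both ages, and the cortical shell of the metaphysis and the mid-diaphysis at 26 wk only, which gave 150 libraries in 32 groups of 4 to 6. The title of the series asks how the programs of energy metabolism differ between these bone compartments, with age and with loading. Libraries held 21303 to 17518198 reads assigned to genes, with a median of 1454145.5. Levels below are normalised read counts (read counts divided by a size factor), given as mean ± SD. Differences are log2 fold changes of the normalised count plus 1, ± SE, from limma over 13791 genes, with Benjamini-Hochberg adjusted p, so they understate the change of genes with low counts.

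Of the 150 libraries, 8 held high levels of 12 mesothelial genes, a list written after the data were examined. Their mean log2 level over the list was 4.98 to 6.97, against 0 to 1.78 in the others (median 0.456). Msln, a surface protein of mesothelial cells, was at 106.96 to 397 in the 8 libraries and had a median of 1.85 in the others (highest 31.9). The cell cycle inhibitor Cdkn2a was at 238 to 1155 against a median of 7.47 (highest 102.3). The highest of these libraries, the loaded cancellous bone of mouse 5d2D, had mean log2 levels of 1.89 for erythroid, 2.00 for neutrophil and 4.95 for osteoblast genes, where the medians of the others were 7.80, 9.00 and 9.51. The remaining 7 came from 26 wk mice: the loaded cancellous bone (5.92) and loaded mid-diaphysis (6.77) of mouse 1hO, the loaded cancellous bone (6.33) and control shell (4.98) of mouse 24hO1, and the loaded cancellous bone (6.88), loaded shell (5.95) and control mid-diaphysis (6.88) of mouse 24hO2. A further library, the loaded cancellous bone of mouse 1h01, held 21303 reads, the lowest depth. Each count below was also computed without these 9 libraries, a choice made after the data were examined. For loading, the other limb of the same mouse and site then drops out too. This leaves mice 24hO3, 24hO4 and 24hONext in 26 wk cancellous bone and shell at 24 h. In 26 wk cancellous bone at 1 h it leaves 1h03 and 1h06. A change of a count can thus also come from fewer mice.

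**Figure D1:**
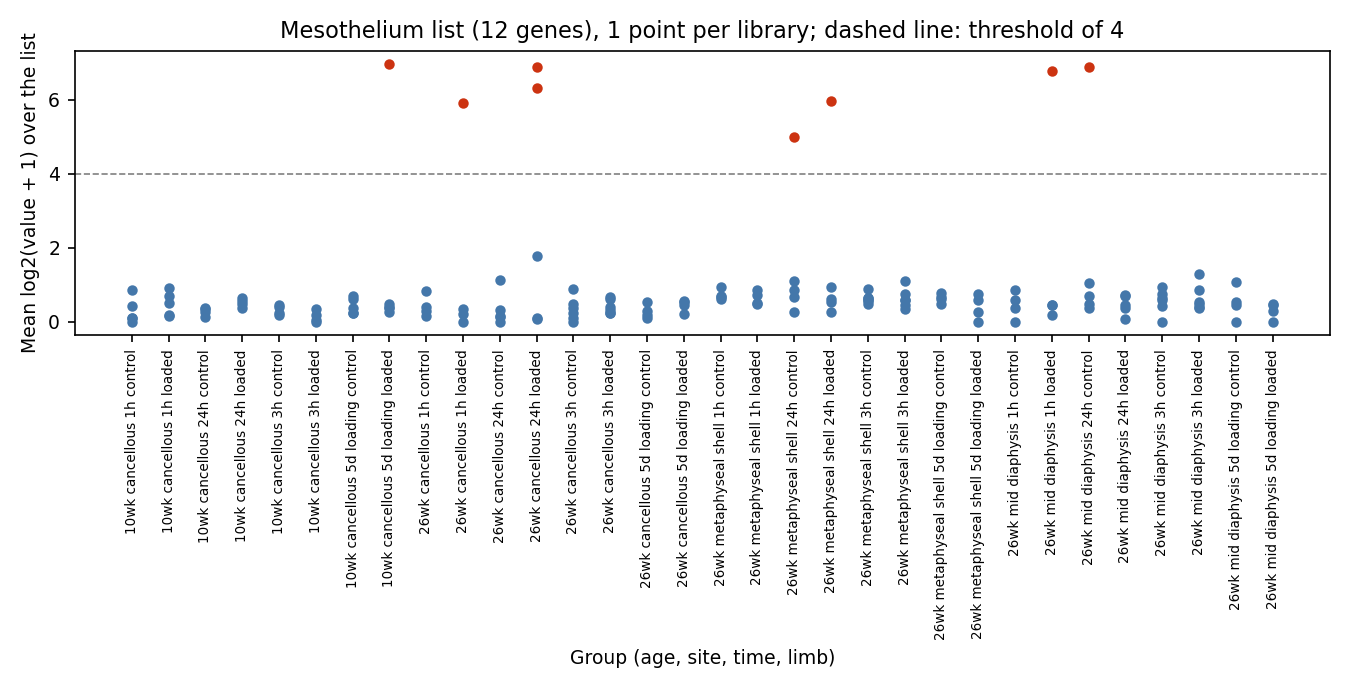
Mean log2(normalised read count + 1) over the 12 genes of the mesothelium list (vertical axis) in each library (1 point) of the 32 groups (horizontal axis); red points lie above the dashed line at 4. The 8 red libraries lie between 4.98 and 6.97, and the others between 0 and 1.78.

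Sites were compared within the control limbs of 26 wk mice. Skeletal muscle genes were far higher in the metaphyseal shell than in cancellous bone. Myh2, a myosin heavy chain of fast muscle fibres (chromosome 11, 67171027 to 67197517, + strand, mm10), was at 593 ± 398 in the shell and 82.4 ± 204 in cancellous bone (n = 19 each), a log2 fold change of 5.00 ± 0.68 (adjusted p = 2.94e-06, higher in 19 of 19 mice). Ckmt2, the mitochondrial creatine kinase of striated muscle, differed by 4.95 ± 0.55, the iron regulator Hfe2 by 4.64 ± 0.57, the sarcomere genes Ldb3 and Acta1 by 4.64 ± 0.63 and 4.63 ± 0.56, and Smpx by 4.63 ± 0.65, each higher in 19 of 19 mice. The interferon-induced GTPase Iigp1 was lower by -0.92 ± 0.23 in 19 of 19 mice. In all, 585 genes were higher and 39 lower in the shell (edgeR called 682 genes, 567 of them shared).

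All 16 muscle genes were higher in the shell (median log2 fold change 4.52), 14 past the threshold over all genes and 16 adjusted over the list alone (camera adjusted p = 4.99e-52, adjusted p = 0.000797 with an estimated correlation). All 8 genes of periosteum, tendon and ligament were higher (median 2.28; 6 past the threshold, 7 adjusted over the list alone, adjusted p = 0.000797 with an estimated correlation). Among them were Aspn at 4.22 ± 0.43, Prg4 at 2.50 ± 0.42 and Postn at 1.43 ± 0.25, all matrix proteins. Of the 35 nuclear genes of respiratory complex I, 34 were higher (median 0.54), 15 past the threshold and 21 adjusted over the list alone; Ndufc1 differed by 0.84 ± 0.18 and Ndufa5 by 1.01 ± 0.21. Complexes III and IV had 20 of 21 genes higher (median 0.46; 8 past the threshold, 12 adjusted over the list alone), with Cox5b at 0.83 ± 0.17 and Cox7b at 0.72 ± 0.16. The tricarboxylic acid (TCA) cycle had 24 of 26 higher (median 0.48; 5 and 10), with Sdhb at 0.84 ± 0.20, and ATP synthase 14 of 15 (median 0.43; 5 and 8), with Atp5g3 at 0.65 ± 0.14. In glycolysis 5 genes were higher and 1 lower past the threshold (6 and 1 adjusted over the list alone). Aldoa differed by 2.02 ± 0.28, Hk2 by 0.96 ± 0.19 (-0.0698 with the muscle list mean as a covariate) and Slc2a3 by -0.81 ± 0.19. In fatty acid oxidation 1 of 19 genes passed either way, Hadh at 0.81 ± 0.25. By camera at its preset correlation these energy lists had adjusted p from 1.17e-13 for complex I to 0.0301 for glycolysis. With an estimated correlation none passed: adjusted p = 0.0721 for complex I, 0.108 for complexes III and IV, 0.117 for the TCA cycle, 0.176 for ATP synthase, 0.262 for glycolysis and 0.304 for fatty acid oxidation.

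The muscle list itself had a mean log2 level of 9.41 ± 1.19 in the shell and 5.27 ± 1.93 in cancellous bone. Genes of marrow stroma were lower in the shell (median -0.52; 7 of 8 lower, 2 past the threshold, 4 adjusted over the list alone, adjusted p = 0.0092 with an estimated correlation), with the stem cell factor Kitl at -0.75 ± 0.17 and the leptin receptor Lepr at -1.30 ± 0.39 (0.026 in loaded limbs). All 21 cell cycle genes were lower (median -0.39) but none passed singly by either count (adjusted p = 0.0441 with an estimated correlation). The osteocyte gene Sost, an inhibitor of Wnt signalling, was higher by 1.06 ± 0.32 (adjusted p = 0.0427). Of 12 Wnt ligands and targets, Wnt16 passed at 2.31 ± 0.39 (camera adjusted p = 0.0167, adjusted p = 0.177 with an estimated correlation). In all, 19 of 35 lists passed camera at its preset correlation and 4 with an estimated one. With the mean of the muscle list as a covariate, chosen after the data were examined, limma called 0 genes (630 at an unadjusted p under 0.05). That mean itself differs strongly between these sites, so the covariate takes up part of the site contrast. The loss of calls thus cannot tell muscle RNA from lower power.

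**Figure D2:**
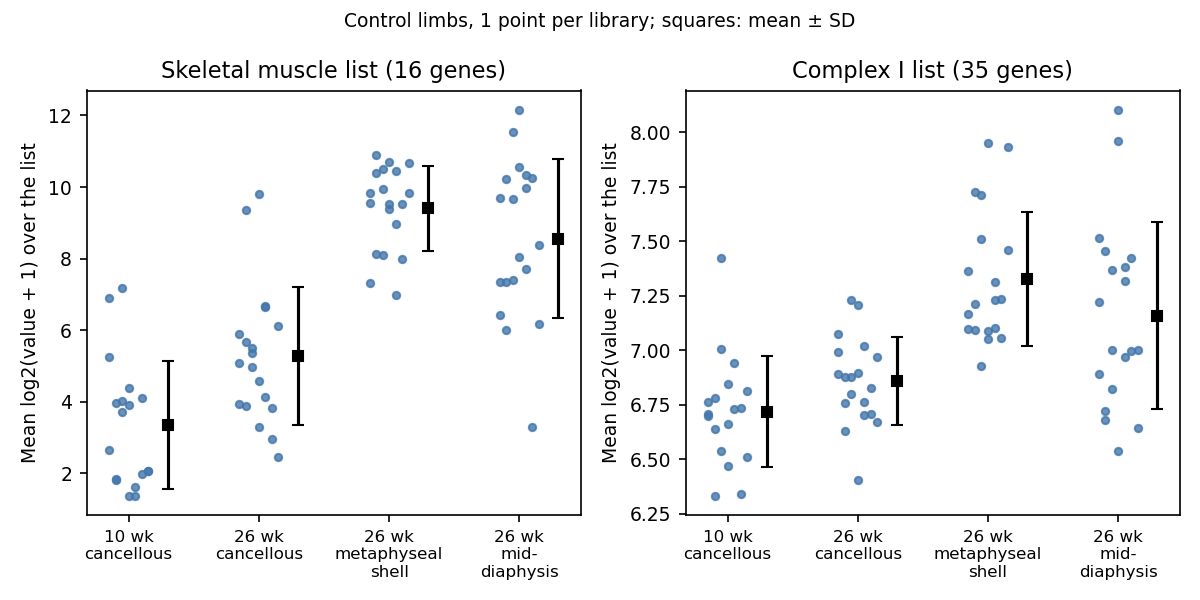
Mean log2(normalised read count + 1) over the skeletal muscle list (left) and the complex I list (right) in control limbs, by age and site; each point is 1 library and squares show mean ± SD. The muscle list averaged 3.35 in 10 wk cancellous bone, 5.27 in 26 wk cancellous bone, 9.41 in the shell and 8.56 in the mid-diaphysis.

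The mid-diaphysis differed from cancellous bone in muscle, marrow, fat and growth cartilage genes. The calcium pump of fast muscle Atp2a1 differed by 4.31 ± 0.58, Pvalb by 4.22 ± 0.61, Sh3bgr by 4.19 ± 0.54, Tnnt3 by 4.18 ± 0.59, Xirp2 by 4.12 ± 0.57 and Acta1 by 4.04 ± 0.58, all higher in 17 of 17 mice with both sites. Lower in 17 of 17 mice were the platelet and endothelial selectin Selp (-2.16 ± 0.34, adjusted p = 1.90e-05), the platelet integrin Itga2b (-1.64 ± 0.28), the lipid desaturase Scd1 (-1.59 ± 0.23), Kng2 (-1.57 ± 0.26), Pappa (-1.52 ± 0.30) and Plek (-1.41 ± 0.22). Sost was at 469 ± 281 in the mid-diaphysis and 94.9 ± 56.4 in cancellous bone (n = 19 each), higher by 2.10 ± 0.33 (4.29-fold, 17 of 17 mice; chromosome 11, 101962458 to 101967015, - strand). In all, 443 genes were higher and 464 lower (edgeR 1129, 812 shared). With the muscle list mean as a covariate limma called 92 genes, with the same limit, since that mean differs between these sites too.

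Muscle genes were higher here too (16 of 16, median 3.81; 14 past the threshold, 15 adjusted over the list alone, adjusted p = 0.00351 with an estimated correlation), and the list averaged 8.56 ± 2.22 in the mid-diaphysis. The TCA cycle had 24 of 26 genes higher (median 0.50; 4 past the threshold, 9 adjusted over the list alone, adjusted p = 0.0476 with an estimated correlation), with Sdha at 0.52 ± 0.13 and Idh3g at 0.77 ± 0.21. Complex I had 33 of 35 higher (median 0.35; 3 past the threshold, 13 higher and 1 lower adjusted over the list alone, adjusted p = 0.105 with an estimated correlation). Glycolysis had 6 higher and 2 lower (8 and 2 adjusted over the list alone, adjusted p = 0.105 with an estimated correlation), with Aldoa at 2.03 ± 0.30, and ATP synthase 3 higher (7 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). No gene of complexes III and IV passed either way (camera adjusted p = 0.00959, adjusted p = 0.393 with an estimated correlation). All 9 hypoxia targets were higher (median 0.80; 1 past the threshold, Ndrg1 at 1.01 ± 0.19, 4 adjusted over the list alone, adjusted p = 0.00263 with an estimated correlation). Adipocyte genes were lower (11 of 12, median -1.13; 6 past the threshold, 10 adjusted over the list alone, adjusted p = 0.00695 with an estimated correlation), with Cfd at -2.68 ± 0.35 and Adipoq at -1.58 ± 0.23. Endothelial (7 of 11 past the threshold, 7 adjusted over the list alone, adjusted p = 0.0476 with an estimated correlation), marrow stroma (5 and 6 of 8, adjusted p = 0.00351) and macrophage genes (5 and 5 of 9, adjusted p = 0.0476) were lower as well. By contrast 3 of 8 genes of periosteum, tendon and ligament were higher (4 adjusted over the list alone, adjusted p = 0.029). Chondrocyte genes were lower in 13 of 13 (9 past the threshold by both counts, adjusted p = 0.088 with an estimated correlation), among them Col9a2 at -4.06 ± 0.78.

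Between the cortical sites, 1 gene was higher and 47 lower in the mid-diaphysis than in the shell (edgeR 54, 34 shared), and no gene met the rule for named genes. The genes named next were chosen after their values were seen. The cartilage collagen Col9a2 (chromosome 4, 121039385 to 121055322, + strand) differed by -4.80 ± 0.78 (adjusted p = 0.00162, lower in 15 of 17 mice), the proteoglycan Acan by -4.08 ± 0.80 and Col10a1, made by hypertrophic chondrocytes, by -3.93 ± 0.76. All 13 chondrocyte genes were lower (5 past the threshold, 8 adjusted over the list alone, adjusted p = 0.0189 with an estimated correlation), as were 12 of 12 adipocyte genes (3 and 9, adjusted p = 0.00529), with Cfd at -2.27 ± 0.35. Hypoxia targets were higher in 7 of 9 (0 past the threshold, 1 adjusted over the list alone, adjusted p = 0.00529). The 1 gene that was higher, at 1.52 ± 0.31, was Rn45s, a ribosomal RNA precursor, which took 8.95 ± 7.08% of reads in the mid-diaphysis and 3.86 ± 3.00% in the shell. The count of 48 fell to 29, 28, 30 and 31 without mouse 1h03, 1h06, 3h01 or 3h04 in turn and was 140 without mouse 24hO4.

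Age was compared in control cancellous bone, on values rescaled to common factors. Gpnmb, a glycoprotein of macrophages and osteoclasts (chromosome 6, 49036546 to 49070929, + strand), was at 41.3 ± 34.5 at 26 wk (n = 19) and 2.36 ± 2.72 at 10 wk (n = 18), higher by 3.32 ± 0.46 (10.0-fold, adjusted p = 5.15e-05). The muscle genes Myl1 (3.01 ± 0.67), Trdn (2.95 ± 0.64), Xirp2 (2.92 ± 0.71), Myh1 (2.82 ± 0.70) and Neb (2.77 ± 0.73) were higher at 26 wk. Lower at 26 wk were the histone gene Hist2h2ac (-1.94 ± 0.53), the small nucleolar RNA Snora30 (-1.88 ± 0.45), Adamts17 (-1.84 ± 0.44), Bfsp1 (-1.73 ± 0.34), the osteocyte marker Pdpn (-1.63 ± 0.36) and Ramp3 (-1.63 ± 0.45). Of 430 called genes 229 were higher (edgeR 752, 403 shared). On values as deposited, a choice made after the data were examined, limma called 633 genes, of which 495 were lower and 338 were shared.

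Glycolysis genes were higher at 26 wk (median 0.34; 14 of 19 higher, 2 past the threshold, 6 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0103), with Aldoa at 1.11 ± 0.27 and Pkm at 0.61 ± 0.17. Genes of complexes III and IV were higher too (median 0.22; 19 of 21 higher, 1 past the threshold, 4 adjusted over the list alone, camera adjusted p = 0.000892), with Uqcrc2 at 0.59 ± 0.18. With an estimated correlation the adjusted p was 0.543 and 0.582. Adipocyte genes were higher in 12 of 12 (1 past the threshold by both counts, Lipe at 1.399 ± 0.28, adjusted p = 0.727 with an estimated correlation). Collagen processing genes were lower in 15 of 20 (2 past the threshold by both counts, Fkbp10 at -1.05 ± 0.22 and P4hb at -0.63 ± 0.17, adjusted p = 0.727 with an estimated correlation). Muscle genes were higher in 15 of 16 (median 2.22; 2 past the threshold, 13 adjusted over the list alone, adjusted p = 0.543 with an estimated correlation); the list averaged 5.27 ± 1.93 at 26 wk and 3.35 ± 1.80 at 10 wk. Rn45s took a mean of 33.0% of reads in 10 wk control cancellous bone at 3 h and 26.9% at 24 h, against 5.06% and 3.93% at 26 wk. At 1 h the shares were 2.27% at 10 wk and 5.37% at 26 wk, and after 5 days 11.9% and 11.05%. Without the 3 h and 24 h groups limma called 14 genes, 4 of them among the 430, and with the muscle list mean as a covariate 166, with 152 among the 430. With this covariate none of the 5 lists passed camera (adjusted p = 0.128 for glycolysis and 0.126 for complexes III and IV). Both alternatives were chosen after the data were examined. In loaded limbs limma called 594 genes, with 184 among the 430. Leaving out 1 mouse gave 234 to 599 genes, with 254 without 24hO4, 275 without 24hONext, 265 without 3hYA, 242 without 3hYB, 234 without 3hYC and 274 without 5dAB.

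Loading was compared with the contralateral limb, first in 10 wk cancellous bone. At 1 h, genes of the immediate early response were higher in 16 of 20 cases (median 0.53), with the AP-1 subunit Fosb at 2.94 ± 0.82 (5 of 5 mice), the 1 member that passed adjusted over the list alone, and Egr2 at 1.54 ± 0.76. The list passed camera (adjusted p = 0.0167, adjusted p = 0.906 with an estimated correlation), as did inflammatory genes (12 of 13 higher, adjusted p = 0.00736, adjusted p = 0.352 with an estimated correlation), with Tnf at 1.55 ± 0.75. No gene passed over all genes at any time: limma called 0 at 1 h, 3 h, 24 h and 5 days, where 398, 1126, 232 and 537 had an unadjusted p under 0.05 (edgeR 0 throughout, with 619, 518, 318 and 501). At 3 h the 1126 fell to 320 without mouse 3hYC, whose loaded library held 339300 reads. At 24 h the 232 became about 1.2e+02 without 24hYA and 503 without 24hYC, and after 5 days the 537 became 836, 858 and 172 without 5d2B, 5d2C or 5d2D in turn. At 3 h chondrocyte genes were lower in 13 of 13 (median -3.15, camera adjusted p = 2.44e-07, adjusted p = 0.837 with an estimated correlation), with Ihh at -3.21 ± 0.89 the 1 member passing adjusted over the list alone, and Sost was at -1.28 ± 0.67. Genes of complexes III and IV were lower in 19 of 21 at 1 h (median -0.30, adjusted p = 0.000118), higher in 18 of 21 at 3 h (0.17; 0.00826), lower in 16 of 21 at 24 h (-0.20; 0.0121) and higher in 19 of 21 after 5 days (0.22; 0.0167). With an estimated correlation the adjusted p was 0.565, 0.837, 0.703 and 0.51 in turn. After 5 days neutrophil genes were lower in 14 of 14 (median -1.50; 9 adjusted over the list alone, adjusted p = 0.153 with an estimated correlation). Osteoblast genes were lower in 14 of 14 (median -0.80; 0 adjusted over the list alone, adjusted p = 0.238 with an estimated correlation). This group holds the loaded limb of mouse 5d2D with its mesothelium level of 6.97. Without the 9 libraries their camera adjusted p was 0.189 and 0.79, and limma called 2 genes at 3 h, where none of the 9 was taken: R3hdm2 at -1.77 ± 0.34 and Ier5l at -3.39 ± 0.63, chosen after their values were seen.

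In 26 wk cancellous bone, 69 genes were higher and 5 lower in the loaded limb at 24 h. The transcription factor Meis2 was at 77.9 ± 97.7 in loaded and 0.602 ± 1.35 in control limbs, higher by 4.71 ± 0.95 (adjusted p = 0.0155, 5 of 5 mice). The protein C receptor Procr was higher by 3.91 ± 0.76 (adjusted p = 0.0138) and Tacc2 by 3.62 ± 0.74, each in 5 of 5 mice. Fgd3 was at 13.2 ± 7.07 in loaded limbs and at 0 in all 5 control limbs. The hepatic lipase Lipc (-2.56 ± 0.61), the progestin receptor Paqr7 (-1.85 ± 0.47) and the adhesion receptor Gpr56 (-1.64 ± 0.40) were lower in 5 of 5 mice. edgeR called 56 genes, 29 of them shared. The loaded limbs of mice 24hO1 and 24hO2 are among the 8 libraries with high mesothelium levels, at 6.33 and 6.88. Without either mouse limma called 0 genes, and without 24hO3, 24hO4 or 24hONext 4, 470 and 307. Without the 9 libraries Meis2 was at 2.90, Procr at 2.42 and Gpr56 at -0.87. Limma then called 4 genes, 2 of them among the 74, all higher and chosen after their values were seen: Uchl5 (3.15 ± 0.60), Cluap1 (3.11 ± 0.60), Arfip1 (2.27 ± 0.44) and Pcbp4 (3.47 ± 0.64).

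Gene lists were tested in the same comparison. Immediate early genes were higher in 17 of 20 (5 adjusted over the list alone), with Atf3 at 3.06 ± 0.83, Jun at 1.499 ± 0.41 and Fos at 2.44 ± 0.75 (adjusted p = 0.0878). Of the mechanoresponsive list 5 genes were higher and 1 lower adjusted over the list alone, with Ankrd1 at 4.96 ± 1.29 and Tnc at -1.35 ± 0.43. Inflammatory genes were higher in 10 of 13 (3 adjusted over the list alone), with the chemokine Cxcl1 at 2.69 ± 0.73. Neutrophil genes were lower in 14 of 14 (median -1.06) and pentose phosphate genes in 6 of 7 (4 adjusted over the list alone), with Pgd at -0.87 ± 0.28. Each of these 5 lists passed camera at the preset correlation, with adjusted p = 0.572 for immediate early genes and 0.523 for the other 4 with an estimated correlation. Without the 9 libraries Atf3 was at 1.87, Jun at 0.69, Fos at 1.13 ± 0.80, Ankrd1 at 3.10, Tnc at -0.76, Cxcl1 at 1.48 and Pgd at -0.48, and none of the 5 lists passed (camera adjusted p of 0.855, 0.57, 0.762, 0.689 and 0.639). At 1 h, 3 h and 5 days limma called 0 genes, with 1930, 415 and 210 at an unadjusted p under 0.05 (edgeR 0, with 200, 462 and 412). At 1 h the 1930 fell to about 1.3e+02 without mouse 1h01, whose loaded library held 21303 reads, and to 155 without the 9 libraries. At 3 h the 415 fell to 262 without 3h03, and after 5 days the 210 fell to about 1.1e+02 without 5dAB. Fosb was at 3.06 ± 0.91 at 1 h (3 of 4 mice) and Nr4a2 at 1.96 ± 0.66, the 2 immediate early members passing adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.999 with an estimated correlation). Without mouse 1hO, whose loaded cancellous library has a mesothelium level of 5.92, limma called 50 genes at 1 h, all lower, with the library of 1h01 still included. Without mouse 1h03 it called 2, and without 1h01, or without the 9 libraries, 0. After 5 days muscle genes were lower in 15 of 16 (median -3.03; 0 adjusted over the list alone, adjusted p = 0.348 with an estimated correlation), beside erythroid genes higher in 10 of 10 (median 0.82, adjusted p = 0.362).

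In the metaphyseal shell, osteoclast genes fell in the loaded limb at 24 h. Dcstamp, a membrane protein needed for fusion of osteoclast precursors (chromosome 15, 39745930 to 39760938, + strand), was at 22.2 ± 12.05 in loaded and 68.01 ± 31.7 in control limbs. It fell by 1.62 ± 0.27 on the log2 scale (3.07-fold; limma adjusted p = 0.0262, edgeR adjusted p = 0.0346; lower in 5 of 5 mice). It was the 1 gene called by limma and by edgeR (594 at an unadjusted p under 0.05, and 1076, 1066 and 334 without mouse 24hO1, 24hO2 or 24hO3). All 13 osteoclast genes were lower (median -0.94), 1 past the threshold over all genes and 10 adjusted over the list alone. Among these were the bone-degrading protease Ctsk at -1.37 ± 0.33, the chloride transporter Clcn7 at -0.96 ± 0.26, the receptor Oscar at -1.37 ± 0.40 and the phosphatase Acp5 at -1.04 ± 0.33. The list passed camera (adjusted p = 5.06e-21, adjusted p = 0.0112 with an estimated correlation) and fry (adjusted p = 0.00887). Neutrophil genes were lower in 14 of 14 (median -0.52; 1 adjusted over the list alone, Camp at -0.81 ± 0.23, adjusted p = 0.307 with an estimated correlation). Complex I genes were higher in 35 of 35 (median 0.37; 0 adjusted over the list alone, adjusted p = 0.791). The control limb of mouse 24hO1 and the loaded limb of 24hO2 had mesothelium levels of 4.98 and 5.95. Without the 9 libraries, which leaves mice 24hO3, 24hO4 and 24hONext here, Oscar was at -0.82 and Dcstamp at -1.37 ± 0.33 (limma adjusted p = 0.351). The osteoclast list then had a camera adjusted p of 1.54e-07 at the preset correlation, and complex I 0.6. An estimated correlation was not run without the 9 libraries. Leaving out mouse 24hO1, 24hO2, 24hO3 or 24hO4 in turn, limma called 0 genes.

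**Figure D3:**
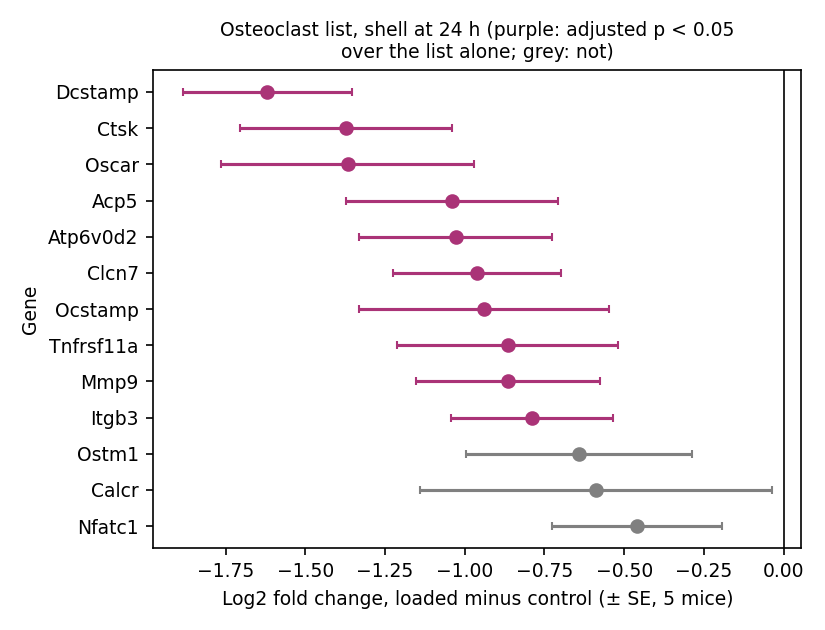
Log2 fold change (loaded minus control limb, ± SE, 5 mice; horizontal axis) of the 13 osteoclast genes in the metaphyseal shell 24 h after loading (vertical axis). All 13 lie below 0, from -1.62 for Dcstamp, and the 10 in purple passed adjusted over the list alone. The SE rests on the spread over all times in the shell, not on these 5 mice alone.

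At the other times limma called 0 genes in the shell: 310, 178 and 1565 had an unadjusted p under 0.05 at 1 h, 3 h and 5 days (edgeR 0 each). The 178 became 275 without mouse 3h06, and the 1565 became 914 without 5dAC and 2553 without 5dAD. At 1 h the immediate early list passed camera (adjusted p = 1.97e-05, adjusted p = 0.357 with an estimated correlation), with Egr1 at 1.18 ± 0.39 (4 of 4 mice) and Fosb at 2.33 ± 0.89 (3 of 4). Muscle genes were lower in 16 of 16 (median -3.42; 12 adjusted over the list alone, adjusted p = 0.137 with an estimated correlation). After 5 days 6 lists of energy metabolism were lower: the TCA cycle in 24 of 26 genes (median -0.63), complex I in 29 of 35 (-0.44), complexes III and IV in 18 of 21 (-0.54; 5 adjusted over the list alone), and ATP synthase in 14 of 15 (-0.52). The other lists were fatty acid oxidation in 17 of 19 (-0.55; 1 adjusted over the list alone) and glycolysis in 14 of 19 (-0.59). Cs, citrate synthase, was at -1.86 ± 0.59, Cox5a at -1.63 ± 0.47, Hadh at -1.13 ± 0.33 and Pfkp at -1.15 ± 0.41. Their camera adjusted p ran from 2.41e-06 to 0.00889, and with an estimated correlation the adjusted p was 0.743 for complex I and 0.655 for the other 5. The mean over energy genes was lower in the loaded limb of 3 of 4 mice and higher in that of 5dAD (0.163). Muscle genes were lower in 16 of 16 in the same limbs (median -2.62; 0 adjusted over the list alone, adjusted p = 0.655). With the muscle list mean as a covariate none of the 6 energy lists passed (camera adjusted p from 0.197 to 0.863), and without mouse 5dAD, whose loaded limb had a muscle list mean of 10.5, limma called 230 genes.

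In the mid-diaphysis Fosb was higher in the loaded limb at 1 h (chromosome 7, 19302696 to 19310051, - strand). It rose to 142.3 ± 99.8 in loaded limbs from 0.548 ± 1.10 in control limbs, by 6.47 ± 1.14 on the log2 scale (limma adjusted p = 0.0235, edgeR adjusted p = 0.00814; 4 of 4 mice). It was the 1 gene called by limma and by edgeR (699 at an unadjusted p under 0.05). Immediate early genes were higher in 18 of 20 (median 0.86; 3 adjusted over the list alone), with Egr1 at 2.45 ± 0.61 and Atf3 at 4.19 ± 1.15 (camera adjusted p = 1.01e-08, adjusted p = 0.152 with an estimated correlation). Timp1 was at 1.02 ± 0.54 and Sost at -1.46 ± 0.50, lower in 4 of 4 mice, neither past the threshold. The loaded limb of mouse 1hO had a mesothelium level of 6.77; without the 9 libraries Sost was at -0.67 ± 0.41 and Fosb at 6.53 ± 1.26 (adjusted p = 0.137), and there, as without mouse 1h03, 1h06 or 1hO in turn, limma called 0 genes.

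At 3 h, Dmp1, a matrix protein of osteocytes (chromosome 5, 104202613 to 104214102, + strand), was at 738 ± 195 in loaded and 121.7 ± 56.5 in control limbs of the mid-diaphysis. The difference was 2.78 ± 0.53 (6.89-fold, 6 of 6 mice), with a limma adjusted p of 0.0813 over all genes; Dmp1 was chosen after its values were seen. Without the 9 libraries, none of which was taken at 3 h, its limma adjusted p was 0.0364 at the same difference. Its SE fell from 0.53 to 0.48, since all times of a site share 1 estimate of the spread. Limma then called 2 genes, Dmp1 and Ttc30a1 (3.26 ± 0.60). Wnt1, a bone-anabolic ligand, was at 30.3 ± 18.3 and 4.02 ± 5.54, different by 3.09 ± 0.75 in 6 of 6 mice (adjusted p = 0.919) and the 1 Wnt member passing adjusted over the list alone. The Wnt list (10 of 12 higher, camera adjusted p = 0.00471) and the mechanoresponsive list (10 of 12 higher; 0.000506) both had an adjusted p of 0.183 with an estimated correlation, with Bmp2 at 1.61 ± 0.59. Egr1 was at 1.36 ± 0.50 in 6 of 6 mice. Limma and edgeR called 0 genes, with 386 and 319 at an unadjusted p under 0.05, and without mouse 3h01 limma called 1.

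**Figure D4:**
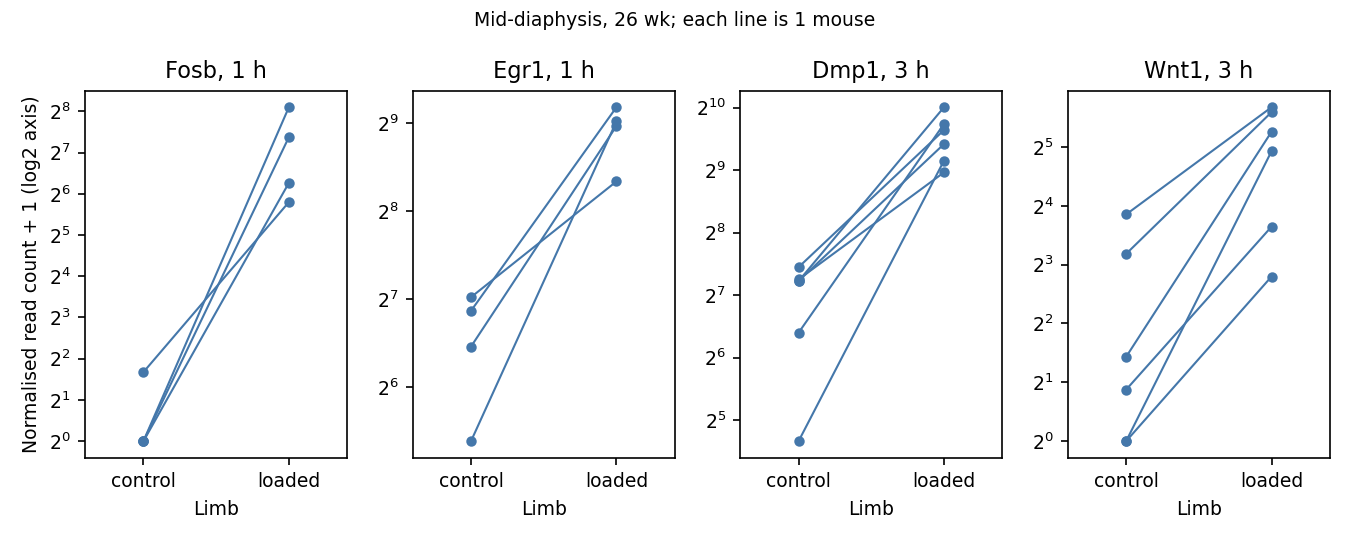
Normalised read count plus 1 (vertical log2 axis) of Fosb and Egr1 at 1 h and of Dmp1 and Wnt1 at 3 h in the control and loaded mid-diaphysis (horizontal axis); each line joins both limbs of 1 mouse. All 4 mice at 1 h and all 6 mice at 3 h were higher in the loaded limb.

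At 24 h osteoblast genes were higher in 12 of 14 in the loaded mid-diaphysis (median 0.74; 1 adjusted over the list alone, the phosphatase Alpl at 1.76 ± 0.45, camera adjusted p = 2.74e-06, adjusted p = 0.202 with an estimated correlation). Osteocyte genes were higher in 7 of 7 (2 adjusted over the list alone, Sost at 1.34 ± 0.45 and Mepe at 1.35 ± 0.47, adjusted p = 0.174 with an estimated correlation). Collagen processing genes were higher in 17 of 20 (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.174), with Creb3l1 at 1.38 ± 0.33 and Fkbp10 at 1.11 ± 0.36. The control limb of mouse 24hO2 had a mesothelium level of 6.88, and without the 9 libraries these 3 lists had camera adjusted p of 0.00102, 0.00719 and 3.87e-09, and Sost was at 0.75 ± 0.36, Mepe at 0.72 and Alpl at 1.17. After 5 days TCA cycle genes were lower in 22 of 26 (3 adjusted over the list alone, Mpc2 at -2.02 ± 0.51, Sucla2 and Me2, camera adjusted p = 0.00637, adjusted p = 0.919 with an estimated correlation). Muscle genes were lower in 16 of 16 (median -1.67, adjusted p = 0.919). Limma called 0 genes at both times (667 and 854 at an unadjusted p under 0.05). edgeR called 0 at 24 h and 4 lower after 5 days (627 and 693 unadjusted), namely Cpsf7, Kazn, Cntn3 and Ift122, chosen after their values were seen. After 5 days limma called 15 genes without mouse 5dAC and 2 without the 9 libraries, none of which belongs to this group, Nbr1 at -3.02 ± 0.56 and Cpsf7 at -3.45 ± 0.64.

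The difference between the loading responses at 26 and 10 wk was tested in cancellous bone. Limma called 0 genes at 1 h, 3 h, 24 h and 5 days, with 1145, 886, 973 and 319 at an unadjusted p under 0.05, and edgeR 0, 0, 1 and 0; the 1 was Procr at 24 h, chosen after its value was seen. The 1145 became 227 without mouse 1h01, with its library of 21303 reads, and 1848 and 1860 without 1h03 or 1h06. The 886 fell to 380 without 3hYC, the 973 to 577, 647 and 633 without 24hO2, 24hYA or 24hYB, and the 319 became 491, 210 and 198 without 5d2C, 5d2D or 5dAB. Without mouse 24hO4 limma called 2 genes at 24 h. At 3 h the difference was negative for 20 of 20 ribosomal protein genes (median -0.51, camera adjusted p = 9.9e-08, adjusted p = 0.293 with an estimated correlation) and for 19 of 21 genes of complexes III and IV (median -0.36, adjusted p = 7.18e-05; 0.591). At 24 h it was positive for 18 of 21 genes of complexes III and IV (median 0.64, adjusted p = 0.472 with an estimated correlation) and for 23 of 26 of the TCA cycle (1 adjusted over the list alone, Idh3b at 1.79 ± 0.51, adjusted p = 0.511). In this group 2 of the 5 loaded 26 wk libraries had high mesothelium levels, and without the 9 libraries both lists missed the threshold (camera adjusted p = 0.386 and 0.543). After 5 days it was positive for 10 of 10 erythroid genes (median 2.14, adjusted p = 0.0855 with an estimated correlation). Adjusted over the list alone 5 passed, with Car1 at 2.60 ± 0.73. The 10 wk loaded limbs include that of mouse 5d2D, with an erythroid level of 1.89, where libraries without high mesothelium levels had a median of 7.80. Without the 9 libraries the camera adjusted p was 5.35e-08 at the preset correlation. In all, 34 of 140 list tests passed camera at the preset correlation and 0 with an estimated one, and 16 passed at the preset correlation without the 9 libraries.

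The difference of the loading response between the 3 sites was tested in 26 wk mice by a limma F test. At 24 h, 28 genes passed (edgeR 95, 18 shared). Mical2, which oxidises actin, had a loading difference of 3.07 ± 0.86 in cancellous bone, 0.30 ± 0.41 in the shell and -3.13 ± 0.86 in the mid-diaphysis (adjusted p = 0.00769). The matrix protein Tnc had -1.35 ± 0.43, -0.63 ± 0.26 and 0.99 ± 0.36 (adjusted p = 0.0384). Both were chosen after their values were seen. Of 7 osteocyte genes, 5 passed adjusted over the list alone and 0 over all genes. Sost had -0.83 ± 0.59, -1.14 ± 0.39 and 1.34 ± 0.45 (adjusted p = 0.00175 over the list alone), Dmp1 had -0.40 ± 0.78, -1.06 ± 0.35 and 1.34 ± 0.58, and Dkk1, Mepe and Ptprz1 also passed. Without the 9 libraries the loading differences of Sost were -0.068 ± 0.51, -1.29 ± 0.48 and 0.75 ± 0.36. Of the mechanoresponsive list 5 of 12 passed over the list alone (1 over all genes), and of immediate early and inflammatory genes 4 each. At this time the loaded cancellous bone of mice 24hO1 and 24hO2, the control shell of 24hO1, the loaded shell of 24hO2 and the control mid-diaphysis of 24hO2 had high mesothelium levels. Without the 9 libraries 8 genes passed, 3 of them among the 28 and neither Mical2 nor Tnc, and Tnc was at -0.76 in cancellous bone. Without mouse 24hO1, 24hO2, 24hO3, 24hO4 or 24hONext the count was 12, 0, 0, and about 1.2e+02 and 1.1e+02.

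At 1 h, 3 h and 5 days the F test called 0 genes, with 1112, 387 and 1015 at an unadjusted p under 0.05, and edgeR called 0, 1 and 6. The 1112 fell to 719 without mouse 1h01. After 5 days only mice 5dAC and 5dAE gave all 3 sites, so the mid-diaphysis was set against the other sites in these mice alone. Counts without 5dAC or 5dAE rest on 1 mouse there, so nothing is concluded from them. The 1 at 3 h was Dmp1, chosen after its values were seen, with a loading difference of -0.06 ± 0.72 in cancellous bone, 1.13 ± 0.32 in the shell and 2.78 ± 0.53 in the mid-diaphysis. Its limma adjusted p was 0.193 over all genes, 9.81e-05 adjusted over the osteocyte list alone and 0.00674 over all genes without the 9 libraries, none of which was taken at 3 h, and its edgeR adjusted p was 0.0282. At 1 h limma called 14 genes without mouse 1hO and 1 without the 9 libraries, the kinase Src. After 5 days 4 genes of the TCA cycle and 3 of complexes III and IV passed adjusted over the list alone. Limma called about 1.3e+02 genes without the 9 libraries, although none of the 9 was taken at this time at 26 wk. All times share 1 estimate of the spread, so these libraries also act on this test.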

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

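The counts of other splits of the samples, the interval on the read depth tests and the mesothelium list were chosen after the results were seen, and the tests of muscle RNA and of RNA from another source were written knowing that the muscle covariate and the doubted libraries changed these results. No biological explanation other than the site, age or loading that the design names was tested.

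The energy lists were higher in the shell and the mid-diaphysis than in cancellous bone, and muscle genes were higher in both too. At an estimated correlation no energy list passed in the shell (camera adjusted p of 0.0721 or more). In the mid-diaphysis the TCA cycle alone passed (0.0476). The slope of the genes of 5 energy lists on the muscle list, within sites among loaded limbs (n = 57 pieces of 21 mice, taken as independent), predicts 82.72% of the shell difference (95% interval 49.1 to 116.4) and 103.6% of the mid-diaphysis difference (61.5 to 145.8), so skeletal muscle RNA in the pieces is a candidate source. These intervals hold the error of the slope alone and take the differences between sites as fixed, so they are too narrow for the share itself. The pooled slope was 0.0901 ± 0.0183. By site the slopes were 0.0606 in cancellous bone, 0.151 in the shell and 0.0670 in the mid-diaphysis, so the share predicted depends on the site whose slope is used. In loaded limbs (n = 19 per site, 3 relations, adjusted by Benjamini-Hochberg) the relation had Pearson r = 0.819 in the shell (permutation p = 4e-05, adjusted 0.00012; Spearman rho 0.882, permutation p = 2e-05; r = 0.891 without the 2 farthest libraries), 0.459 in the mid-diaphysis (permutation p = 0.0479, adjusted 0.0718; rho 0.340, permutation p = 0.154; 0.147 without these) and 0.396 in cancellous bone (permutation p = 0.0934, adjusted 0.0934; rho 0.228, permutation p = 0.347; -0.122 without these). Without the doubted libraries r was 0.811 in the shell (n = 18), 0.562 in the mid-diaphysis (n = 18) and 0.714 in cancellous bone (n = 15). With log2 reads as a covariate the median difference was 0.392 in the shell (83.6% kept, 43.6 to 123.5) and 0.263 in the mid-diaphysis (76.2%, 19.4 to 132.97), intervals too wide to exclude read depth. A difference of bone itself stays open, as untested: with the muscle covariate, complex I and complexes III and IV had a camera adjusted p of 0.0426 and 0.00358 at the preset correlation in the shell and the TCA cycle 0.0197 in the mid-diaphysis. At an estimated correlation, run only without the covariate, the adjusted p was 0.0721, 0.108 and 0.0476.

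In the loaded shell after 5 days the energy lists were lower by camera at the preset correlation, as were muscle genes, but none passed at an estimated one (adjusted p of 0.743 for complex I and 0.655 for the others). The fall was in 3 of 4 mice: in 5dAD the means over the energy and muscle genes were higher in the loaded limb, by 0.163 and 0.932 on the log2 scale. The muscle slope at the other times (n = 15) predicts 89.01% of the difference (95% interval 60.1 to 117.9), so less muscle RNA in these loaded pieces is a candidate source. This interval holds the error of the slope alone and takes the mean differences over the 4 mice as fixed, so it is too narrow for the share itself. With log2 reads as a covariate the median was -0.644 (124.1% kept, 7.33 to 241), which leaves read depth open. A response of bone to loading stays open, as untested.

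In 26 wk cancellous bone at 24 h, 50 of the 69 genes called higher in loaded limbs, 72.46%, lie at least 1 (log2) higher in the unloaded mid-diaphysis of mouse 24hO2 than the median of the 4 other libraries of its group (median difference 2.07; 22.1% of all genes do so), so RNA of another source in the loaded libraries of mice 24hO1 and 24hO2 is a candidate cause. With log2 reads as a covariate the median of the 69 genes was 2.64 against 2.92 (90.5% kept, 66.3 to 114.7), so most of the difference was kept. Limma then called 19 genes, 16 of them among the 69. Read depth is not excluded, since the loaded library was deeper than the control library in every mouse (group medians 2550943 and 835528 reads). The 69 genes were also called in these same libraries. The mid-diaphysis library is of mouse 24hO2 itself, so the overlap cannot tell RNA of another source from a trait of that mouse. Without the 9 doubted libraries limma called 4 genes, in a fit that keeps mice 24hO3, 24hO4 and 24hONext of this group. Fewer mice can also lower that count. A response to loading stays open for these genes, as untested.

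Other splits of the same samples tell whether chance can be excluded. It can for age (430 genes; 1 of 100 splits as large, highest other 5), shell against cancellous bone (624; 1 of 100, highest other 0), mid-diaphysis against cancellous bone (907; 1 of 100, highest other 297) and mid-diaphysis against shell (48; 1 of 100, highest other 22). It cannot, over splits that also break up the mice the fit blocks on, for loading at 24 h in 26 wk cancellous bone (74 genes; 20 of 100, highest other 1164) and in the shell (1 gene; 26 of 100, highest other 286) or at 1 h in the mid-diaphysis (1 gene; 7 of 35, highest other 6). Among the 15, 10 and 8 splits in turn that part as many pairs as the real one, which is included, none of the others was as large (highest 38, 0 and 0), but these are too few for a share under 0.05. It cannot either for the loading response between sites at 24 h (28 genes; 9 of 100, highest other about 1.1e+02). For loading, the highest counts came from splits that put both limbs of some mice on 1 side, so the contrast rests on the other mice. In 26 wk cancellous bone at 24 h the highest other was 1164 over all splits and 38 among those parting every pair. Such counts do not by themselves show a structure of the samples. The source of high counts in the other splits was not tested. For age the splits exchange mice within a time, so they cannot exclude a technical difference that goes with age and time. At 3 h and 24 h Rn45s took 33.0 and 26.9% of reads in 10 wk control cancellous bone, against 5.06 and 3.93% at 26 wk. Without these 2 times most of the 430 calls were lost, as given with the age results. Such a difference stays open for age.

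Where limma called 0 genes any split is as large by construction, so these counts of splits say nothing about chance. In 10 wk cancellous bone these were 100 of 100 splits at 1 h (highest other 78), 35 of 35 at 3 h (96), 35 of 35 at 24 h (7) and 100 of 100 after 5 days (1028). In 26 wk cancellous bone these were 35 of 35 at 1 h (1874), 100 of 100 at 3 h (about 1.5e+02) and 35 of 35 after 5 days (0). In the shell the highest other was 0 at 1 h (35 of 35), 39 at 3 h (100 of 100) and 997 after 5 days (35 of 35), and in the mid-diaphysis 0 at 3 h (100 of 100), 271 at 24 h (100 of 100) and 199 after 5 days (35 of 35). Among splits that part both limbs of every mouse, the highest other was 0, 0, 1 and 1 in 10 wk cancellous bone. In the same order of times it was 0, 1 and 0 in 26 wk cancellous bone. It was 0, 0 and 95 in the shell and 0, 5 and 3 in the mid-diaphysis. For the response between ages the highest other was 0, 1, 10 and 0 at 1 h, 3 h, 24 h and 5 days, and between sites 121, 1 and 28 at 1 h, 3 h and 5 days, with 100 of 100 splits as large each time.

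Of list tests, chance can be excluded for sites at the preset correlation (46 lists; 1 of 100 splits, highest other 39) and at an estimated one (15; 1 of 100, highest other 2). It cannot for loading (125 tests; 12 of 100, highest other 140; at an estimated correlation 1 list, the osteoclast genes of the shell at 24 h; 36 of 100, highest other 9), for the response between ages (34; 17 of 100, highest other 52) or for age (5; 33 of 100, highest other 18). The splits for loading swap the limbs within mice and count lists over all 560 tests together, so the osteoclast list was not tested by itself. At the preset correlation a median of 97 loading tests passed in the other splits, against the real 125. The median was 27 for the response between ages, against 34, and 3 for age, against 5. At an estimated correlation 0 lists passed for the response between ages (100 of 100, highest other 5) and for age (100 of 100, highest other 1), where any split is as large by construction and chance was not tested.

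Single libraries stood apart from their group by the gap to the nearest, tested in 32 groups per measure, where chance flags about 1 in 20 groups. The mesothelium level did so in 7 groups: 6.97 in the loaded 10 wk cancellous bone of mouse 5d2D (next 0.489), 5.92 and 6.77 in the loaded cancellous bone and mid-diaphysis of 1hO (0.355 and 0.458), 1.13 and 4.98 in the control cancellous bone and shell of 24hO1 (0.305 and 1.1), and 5.95 and 6.88 in the loaded shell and control mid-diaphysis of 24hO2 (0.946 and 1.04). Rn45s did in 4 control groups: 46.9% of reads in the 10 wk cancellous bone of 3hYD (next 29.4), 10.5% and 14.1% in the 26 wk cancellous bone of 1h03 (4.28) and 3h03 (4.5), and 13.9% in the mid-diaphysis of 3h01 (7.79). Reads did in 2: 8235955 in the loaded 10 wk cancellous bone of 5d2E (next 3338396) and 1928625 in the control shell of 1h01 (1190672). The muscle list did in 3: 10.5 in the loaded shell of 5dAD (next 6.86), 11.5 in the control mid-diaphysis of 5dAC (8.05) and 3.31, the lowest, in the control mid-diaphysis of 24hO2 (8.38).

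The loading response differed between sites at 24 h for 28 genes by the F test, a count as large in 9 of 100 splits, so chance is not excluded. Between ages in cancellous bone the response differed for 2, 7, 11 and 14 of 35 lists at 1 h, 3 h, 24 h and 5 days. This was by camera at the preset correlation, and 0 lists passed at an estimated one. Over all times the 34 list tests were as many in 17 of 100 splits, so chance is not excluded here either.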

How the results depend on the processing

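The fits without the 9 doubted libraries, with the muscle list mean as a covariate, for age without the 3 h and 24 h groups and on values as deposited, and those leaving out each mouse for age and site were chosen after the results were seen; the other alternatives were planned before the data were examined. Counts are of genes called by limma unless edgeR is named, and the cause of each change was not tested. For loading at a time and site without a doubted library, leaving these out keeps the differences and changes only the shared estimate of the spread.

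For loading in 10 wk cancellous bone the count of 0 at 3 h was 1 with a pseudocount of 0.25, 3 without a filter and 2 without the doubted libraries, and the 0 at 24 h was 6 without a filter. In 26 wk cancellous bone the 74 genes at 24 h became 35 with a minimum mean of 5, 48 without the block for mouse, 0 in a fit to the comparison's libraries alone and 4 without the doubted libraries. Leaving out 1 mouse gave 0 to 470 there (0 without 24hO1 or 24hO2, 4 without 24hO3, 470 without 24hO4, 307 without 24hONext) and 0 to 50 at 1 h (50 without 1hO, 2 without 1h03).

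In the shell the 1 gene at 24 h, Dcstamp, was lost without the block for mouse (0), in a fit to the comparison's libraries alone (0), without the doubted libraries (0) and without mouse 24hO1, 24hO2, 24hO3 or 24hO4 (0 to 1 over all mice). The 0 at 1 h was 19 in the fit to its own libraries, and leaving out 1 mouse gave 0 to 230 after 5 days (230 without 5dAD).

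In the mid-diaphysis the 1 gene at 1 h, Fosb, was lost with a pseudocount of 0.25, without a filter, in a fit to its own libraries, without the doubted libraries and with the muscle covariate (0 each), and without mouse 1h03, 1h06 or 1hO (0 to 1 over all mice). At 3 h the 0 was 1 in a fit to its own libraries, 2 without the doubted libraries and 0 to 1 leaving out 1 mouse (1 without 3h01). At 24 h it was 1 without a filter. After 5 days it was 4 by edgeR, 2 without the doubted libraries, 1 with the muscle covariate and 0 to 15 leaving out 1 mouse (15 without 5dAC).

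For the loading response between ages at 24 h the 0 was 2 without a filter, 1 by edgeR and 0 to 2 leaving out 1 mouse (2 without 24hO4). Between sites, the 28 genes at 24 h became 43 with a pseudocount of 0.25, 12 without a filter, 95 by edgeR, 8 without the doubted libraries and 0 to about 1.2e+02 leaving out 1 mouse (12 without 24hO1, 0 without 24hO2 or 24hO3, 1.2e+02 without 24hO4, 1.1e+02 without 24hONext). The 0 at 1 h was 1 without the doubted libraries and 0 to 14 leaving out 1 mouse (14 without 1hO). At 3 h the 0 was 1 by edgeR and 1 without the doubted libraries. After 5 days only mice 5dAC and 5dAE gave all 3 sites. A count without either thus rests on 1 mouse for the mid-diaphysis, and nothing is concluded from it. The 0 after 5 days was 8 with a pseudocount of 0.25, 3 without a filter, 6 by edgeR, about 1.3e+02 without the doubted libraries and 0 to 462 leaving out 1 mouse (462 without 5dAC).

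The 430 genes of age became 275 without a filter, 752 by edgeR, 14 without the 3 h and 24 h groups, 166 with the muscle covariate and 234 to 599 leaving out 1 mouse (254 without 24hO4, 275 without 24hONext, 265 without 3hYA, 242 without 3hYB, 234 without 3hYC, 274 without 5dAB). Of the 14, 4 were among the 430. In loaded limbs limma called 594 genes for age, 184 of them shared. The 624 genes of shell against cancellous bone became 0 with the muscle covariate, and the 907 of mid-diaphysis against cancellous bone 92. In loaded limbs these comparisons gave 465 and 714 genes, with 321 and 204 shared. The 48 of mid-diaphysis against shell became 31 without the block for mouse, 398 in loaded limbs and 28 to 140 leaving out 1 mouse (29 without 1h03, 28 without 1h06, 140 without 24hO4, 30 without 3h01, 31 without 3h04).

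Of 840 list tests 210 passed camera at the preset correlation and 16 with an estimated correlation. By family the change was from 125 to 1 for loading, from 34 to 0 for the response between ages, from 5 to 0 for age and from 46 to 15 for site. Without the doubted libraries the 34 tests between ages became 16, and with the muscle covariate the 5 for age became 0.

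Some genes changed sign. In loaded limbs in place of control limbs, Lepr in shell against cancellous bone went from -1.30 to 0.026, and in mid-diaphysis against cancellous bone Ndufv1 went from 0.67 to -0.11 and Eci1 from 0.92 to -0.12. With the muscle covariate, Hk2 went from 0.96 to -0.0698 and Uqcrq from 0.58 to -0.00788 in the shell, and Hk2 from 0.79 to -0.0862 in the mid-diaphysis.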

Other observations

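The tests of the doubted libraries and the mesothelium levels were chosen after the results were seen. Sost moved in different directions by time in the mid-diaphysis, at -1.46 ± 0.50 at 1 h (lower in 4 of 4 mice) and 1.34 ± 0.45 at 24 h (higher in 4 of 5), neither past the threshold over all genes (limma adjusted p = 0.947 and 1), and its change between times was not tested. Without the doubted libraries it was at -0.67 ± 0.41 and 0.75 ± 0.36.

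The loaded cancellous bone and control mid-diaphysis of mouse 24hO2 had mesothelium levels of 6.88 each, and the loaded cancellous bone of mouse 5d2D, of another age and time, 6.97. Gata6 was at 87.9 to 614 and Wt1 at 42.9 to 223 in the 8 libraries, against medians of 0 in the others (highest 14.2 and 6.45). RNA from a source shared between libraries is a candidate explanation for these. Over the mesothelium list the control mid-diaphysis of 24hO2 differed from the 5d2D library by a mean log2 of -0.00633 (SD over genes 0.172). The control shell of 24hO1, the lowest, differed by -2.01 (SD 0.614). Of the genes called higher in loaded 26 wk cancellous bone at 24 h, 72.46% lie at least 1 (log2) higher in the control mid-diaphysis of 24hO2. The reference is the median of the 4 other libraries of its group, and 22.1% of all genes do so. Both pieces are of mouse 24hO2, so this overlap cannot tell a shared source from a trait of that mouse. Where that RNA came from was not tested.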
